A study of Mus musculus with 16 samples.

How the data were processed

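PolyA RNA of mouse gonadal fat was sequenced in 16 libraries, 4 in each of 4 groups (sham surgery or sDVX, vehicle or SHU9119). The deposited table holds counts per gene, made by the authors, with genes named by NCBI gene number. Bcl2fastq, TopHat and edgeR and the mm10 build were used by the authors, per the submitters' processing notes, without versions. The counting tool, the annotation and the strand setting are not given in the sources used here. The values were checked to be whole numbers with a different total in each column, and no further step by the authors is recorded.

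Of 24454 genes, 24374 gene numbers were matched to a reference annotation of the same build, which gave symbols and coordinates. The 80 without a match held 0.557% to 1.24% of the counts of a library, mostly gene number 100861531 (0.527% to 1.22%). Library totals were 20425295 to 30889052 counts, and the 10 most abundant genes took 6.91% to 16.2%. All 24 pairs of replicates were checked for duplicates on genes with at least 20 counts, and chi-square per degree of freedom was 11.8 to 203.9, so no pair was a copy. The biological coefficient of variation was 50% (common dispersion) and 22.8% (median over genes).

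Counts were analyzed in R 4.3.3 with edgeR 4.0.16. Of 21661 genes with any count, 16682 were kept by filterByExpr by group and scaled by TMM factors. A quasi-likelihood model with robust dispersion, 1 mean per group and 12 residual degrees of freedom was fitted to all 16 libraries. The contrasts were SHU9119 in sham and in sDVX mice, sDVX under vehicle and under SHU9119, their interaction, and each factor averaged over the other, with F tests and Benjamini-Hochberg adjusted p under 0.05. Standard errors were the log2 fold change over the root of F. Log2 CPM used a prior count of 2. The design, the gene lists, the rule for named genes and the alternatives other than those listed below as later were fixed before the data were examined.

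Genes were named by rule: in each simple comparison and the interaction, among genes past the threshold with a mean of at least 5 CPM, the 8 largest changes in each direction (4 in the averaged comparisons), or the 5 smallest p where fewer than 5 passed. Unnamed gene models, immunoglobulin and T-cell receptor segments and mitochondrial genes were left out of these. The 4 members with the smallest p of each called list were added, of which only some are printed. Lep, Adipoq, Pparg, Fasn, Scd1 and Ucp1 were given throughout. Ucp1 did not pass the filter, so it has no test. Other genes printed were chosen after their values were seen. A gene that the rule names is not reported here.

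Of 37 gene lists for fat metabolism, stress, immune and other cell types, 35 had at least 5 members after the filter. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of a comparison. The blood list (4 of 11 members) and the pancreas list (1 of 13) were not tested. Members were counted as past the threshold over all genes and adjusted over the list alone. A list of 12 ciliated epithelium genes and permutation tests of mean list scores per library were added after the data were seen. Marker sums and scores were compared by exact two-sided permutation of 4 against 4 libraries (70 assignments) or within strata (4900 assignments).

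Alternatives were DESeq2 size factors, no low-count filter, non-robust dispersion, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, the replicate number as a block, 1 surrogate variable (sva 3.50.0), only the 2 groups compared, and leaving out each library in turn. Added after the data were seen were fits without the 6 libraries with at least 500 CPM of epididymis or testis markers, without VX_Veh4 and VX_SHU4, and with epididymis and testis marker sums, or these and the ciliated sum, as covariates.

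The pipeline was tested on simulated data with 16559 genes passing the filter. For SHU9119 in sham mice it recovered 20%, 64%, 88% and 86% of 50 genes each changed by 1.5, 2, 3 and 4 times, with 4 false calls among 16359 unchanged genes. With no simulated change it called 0 of 16559 genes for sDVX under vehicle and 0 for SHU9119 after sDVX. It called the 1 raised list and 0 of 100 unchanged lists. The simulated genes were drawn independently of each other, with no tissue that differed between libraries, so these rates need not hold for the real libraries. Other splits of the real libraries called a median of 12 of the 35 lists for SHU9119 in sham mice.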

Results

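Gonadal fat of lean male C57BL/6J mice, an inbred laboratory strain, was profiled by sequencing of polyadenylated RNA in a crossed design of 2 surgeries and 2 infusions. The mice were 16 weeks old and ate chow. The surgeries were sham surgery and subdiaphragmatic vagotomy (sDVX), in which branches of the vagus nerve are cut below the diaphragm. From 4 weeks after surgery, vehicle or SHU9119 was infused into the cerebral ventricles at 1 nmol per day for 2 weeks. SHU9119 is a peptide that blocks melanocortin receptors of the brain, and calorie intake was matched between groups during the infusion. Each of the 4 groups held 4 libraries. They are named here Sham_Veh, Sham_SHU, VX_Veh and VX_SHU with the replicate number. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries. The series asks whether a path from brain melanocortin receptors through the vagus nerve changes fat tissue independently of energy intake.

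Library totals ran from 20425295 to 30889052 counts, and 18227 to 20253 genes had at least 1 count. Totals did not differ in any of the 4 comparisons of single groups (exact permutation p from 0.6 to 0.971, two-sided). Scd1, which desaturates stearoyl-CoA, alone took 1.28% to 7.35% of the counts of a library. Adipoq, the adipocyte hormone adiponectin, stood at 2863 ± 752 CPM, counts scaled to library size (SD, n = 4), in the Sham_Veh libraries and at 2845 ± 244 in Sham_SHU, 2298 ± 808 in VX_Veh and 2712 ± 459 in VX_SHU.

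Transcripts typical of neighbouring tissue were present in some libraries, and their source was not settled. The summed level of the epididymis markers, led by the secreted protein gene Crisp1, reached 11820 CPM in VX_Veh4, 12540 in VX_SHU4, 3854 in Sham_SHU4 and 1947 in Sham_SHU3. It was 760.8 CPM in Sham_Veh3, 644.7 in Sham_Veh4 and 8.739 to 68.49 in the other 10 libraries. The testis and sperm markers, among them the protamine genes Prm1 and Prm2, summed to 2953 CPM in Sham_Veh4 and 1465 in Sham_SHU3. Genes of motile cilia, a list of 12 genes chosen after the data were seen because they led the first principal component (37.3% of the variance), averaged 337.5 ± 243 CPM in Sham_Veh and 545.8 ± 625 in VX_Veh (SD, n = 4). The corresponding averages were 57.5 ± 79.2 CPM in Sham_SHU and 71.62 ± 110 in VX_SHU. The difference between infusions in this sum gave an exact permutation p of 0.143 after sham surgery and 0.114 after sDVX. Of the marker lists for other tissues and cell types, none passed the exact test after adjustment in any comparison of single groups (lowest adjusted p = 0.214). The smallest exact permutation p is 0.0286, so that a list could pass only if most lists reached it together.

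**Figure D1:**
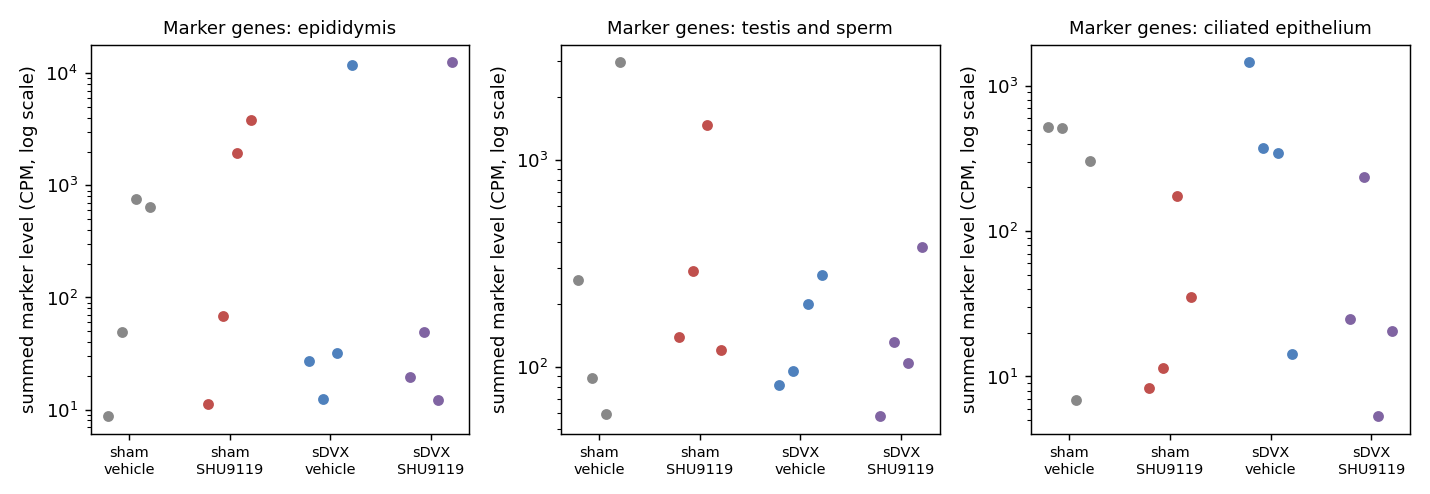
Summed level of marker genes of epididymis, testis and sperm, and ciliated epithelium in each of the 16 libraries, in CPM on a log axis; each point is 1 library, colored by group. Epididymis markers reach 11820 CPM in VX_Veh4 and 12540 CPM in VX_SHU4, and ciliated epithelium markers reach 1451 CPM in VX_Veh1.

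The first comparison asked what SHU9119 did in mice with an intact vagus. Several genes of lipid synthesis were among those that passed, higher in Sham_SHU than in Sham_Veh libraries. Scd2, a stearoyl-CoA desaturase, rose from 272.3 ± 54.9 to 1080 ± 308 CPM (SD, n = 4), a log2 fold change of 1.99 ± 0.266 (SE; adjusted p = 0.0271 by the edgeR quasi-likelihood test). Insig1, which holds the sterol-sensing machinery in the endoplasmic reticulum, rose from 189.9 ± 19.1 to 677.7 ± 227 CPM, by 1.84 ± 0.296 on the log2 scale (edgeR adjusted p = 0.0415). The cholesterol synthesis enzymes Lss (1.73 ± 0.291) and Dhcr7 (1.42 ± 0.20) rose as well, and so did Mogat2, which acylates monoacylglycerol, from 1.747 ± 0.199 to 13.81 ± 6.06 CPM (2.98 ± 0.395).

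In all, 19 of 16682 genes passed, 16 higher and 3 lower. Further genes that rose were the tubulin gene Tuba1a (1.95 ± 0.321 on the log2 scale), Olfm1 (1.43 ± 0.220) and Fmr1, which encodes an RNA-binding protein (1.19 ± 0.173). Cbx7, a Polycomb protein, fell by 0.84 (SE 0.143), Srpx fell by 0.71 (SE 0.118) and Dido1 fell by 0.51 (SE 0.0831). Lep, which encodes leptin, stood at 481.9 ± 182 CPM in Sham_Veh and 1022 ± 267 in Sham_SHU (SD, n = 4), a log2 difference of 1.08 that did not pass (edgeR adjusted p = 0.147). Fasn, the fatty acid synthase (1.84, adjusted p = 0.0962), Scd1 (1.35, adjusted p = 0.103), Pparg, the main transcription factor of fat cells (0.17, adjusted p = 0.688), and Adipoq (−0.01, adjusted p = 0.984) did not pass either. On mm10, Mogat2 lies at chromosome 7 from 99219084 to 99238611, Scd2 at chromosome 19 from 44293676 to 44306864, and Insig1 at chromosome 5 from 28071412 to 28078662. Scd2 and Scd1, and Tuba1a and other tubulin genes, are close copies whose reads the counting could have split.

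Grouped by list, 12 of 35 gene lists were called in this comparison with the preset correlation and 0 with a correlation estimated per list. Cholesterol synthesis and uptake had 3 of 22 members that rose over all genes and 17 adjusted over the list alone, with a median log2 fold change of 0.87; besides Insig1, Lss and Dhcr7 the latter held Idi1 (0.97 ± 0.176), which isomerizes isopentenyl diphosphate. Its adjusted p was 7.2e-20 with the preset correlation, and adjusted p = 0.0761 with an estimated correlation. Of the 22 fatty acid synthesis genes 1 rose over all genes, Scd2, and 14 adjusted over the list alone, such as Acly (2.38 ± 0.530), which makes cytosolic acetyl-CoA, and Acss2 (2.16 ± 0.546), which makes it from acetate. This list gave 2.54e-13, and adjusted p = 0.297 with an estimated correlation. Of 27 extracellular matrix genes 0 passed over all genes, while 15 rose and 2 fell adjusted over the list alone, including the collagen VI chains Col6a1 (0.68 ± 0.129) and Col6a2 (0.96 ± 0.175). The list was called up at 1.05e-09, and adjusted p = 0.297 with an estimated correlation.

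Of 20 genes of glucose uptake and glycolysis, 11 rose adjusted over the list alone and 0 over all genes, among them Tpi1 (0.70 ± 0.150) and Pkm (0.83 ± 0.196); the list gave 1.34e-08, and adjusted p = 0.356 with an estimated correlation. Of 14 genes whose level follows fat mass, 7 rose and 1 fell adjusted over the list alone, among them Bmp3 (1.95 ± 0.432) and Npr3 (1.12 ± 0.292), and 0 passed over all genes. That list gave 7.37e-06, and adjusted p = 0.297 with an estimated correlation. Triglyceride assembly and fatty acid uptake had 5 of 19 members up adjusted over the list alone and 0 over all genes, with Dgat2 (1.08 ± 0.262), which makes triglyceride, among them; it gave 3.79e-05, and adjusted p = 0.607 with an estimated correlation. Oxidative phosphorylation (28 members, median 0.22) and fatty acid oxidation (22 members, median 0.21) were called up with 0 members past the threshold either way, and adjusted p = 0.673 and adjusted p = 0.749 with an estimated correlation. The cell cycle list was called up with 2 of 28 members up adjusted over the list alone (median 0.20), and adjusted p = 0.607 with an estimated correlation. Its median was 0.12 without Sham_Veh2 or Sham_Veh3 and 0.76 without Sham_Veh4, that of fatty acid oxidation 0.36 without Sham_Veh3, and that of triglyceride assembly 0.195 in place of 0.33 without Sham_SHU2. The ciliary gene sum was lower in the Sham_SHU than in the Sham_Veh libraries, beside these groups, at 57.5 against 337.5 CPM.

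Markers of mesothelium, the lining of the depot, were called down (median −0.64, 0 of 14 members past the threshold either way). Markers of granulocytes and mast cells (median −0.52, 0 of 16) and of nerve and Schwann cells (median −0.43, 0 of 14 over all genes and 1, the cadherin gene Cdh19, adjusted over the list alone) were called down too. Each had adjusted p = 0.607 with an estimated correlation. These calls were lost without some libraries: mesothelium at adjusted p = 0.0934 without Sham_SHU1 (and its median was −0.41 without Sham_Veh3), granulocytes and mast cells at 0.174 without Sham_Veh3, and nerve at 0.0505 to 0.182 without any of Sham_Veh3, Sham_Veh4, Sham_SHU1, Sham_SHU2, Sham_SHU4 and VX_Veh or VX_SHU libraries other than VX_Veh1 and VX_SHU4.

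The number of calls depended on single libraries, while in each of the 16 fits without 1 library all 19 genes kept their sign, with a median size of 1.08 to 1.28 against 1.11 on the log2 scale. Those fits share most libraries with the full fit that picked the genes, and the ones without a VX library keep all sham libraries. Leaving out Sham_Veh1, Sham_Veh2, Sham_Veh3, Sham_SHU1, Sham_SHU2, Sham_SHU4, VX_Veh2 or VX_SHU1 gave 0 calls, and leaving out Sham_Veh4, VX_Veh3, VX_Veh4, VX_SHU2 or VX_SHU4 gave 2, 1, 4, 5 and 2, whereas leaving out Sham_SHU3, VX_Veh1 or VX_SHU3 gave 982, 527 and 178. DESeq2 called 1205 genes and limma-voom with sample weights 3868.

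**Figure D2:**
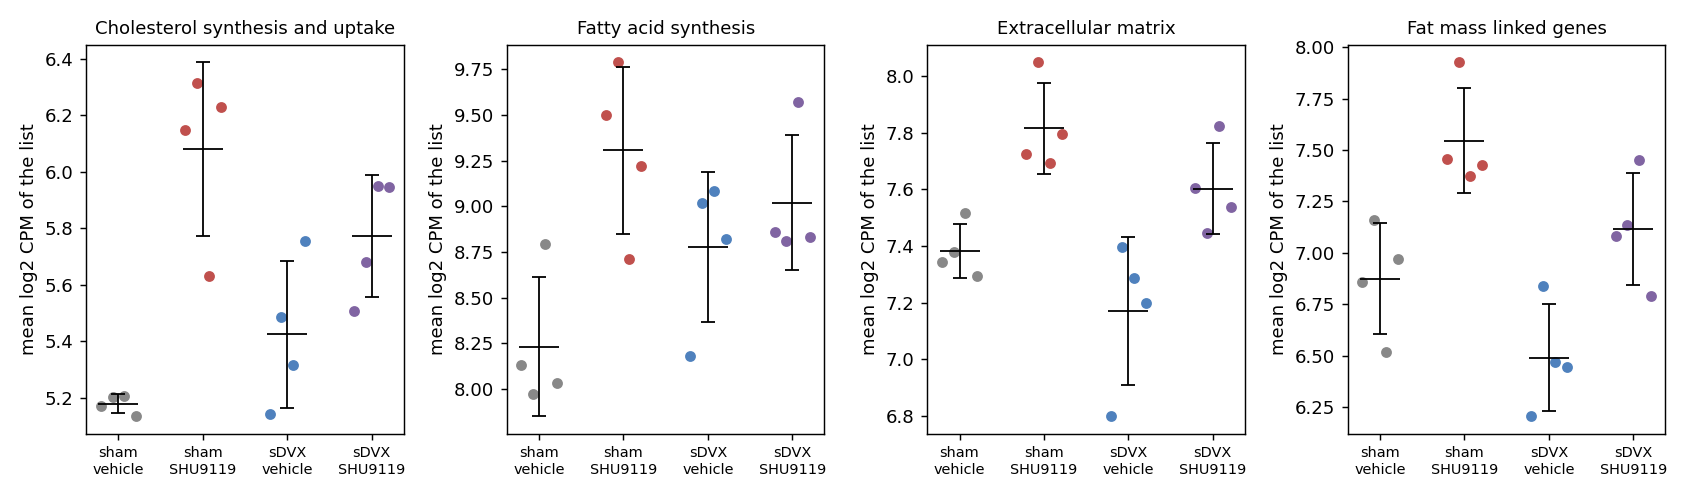
Mean log2 expression of the members of gene lists in each of the 16 libraries, by group; each point is 1 library. The cholesterol list differs between Sham_SHU and Sham_Veh libraries by 0.90 log2 units without overlap of the libraries. Its exact permutation p is 0.0286, the smallest that 70 assignments can give, and its p adjusted over the tested lists is 0.333. The fat mass and extracellular matrix lists have the same exact and adjusted p in this comparison.

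The second comparison asked what SHU9119 did after sDVX. Emp1, an epithelial membrane protein gene, rose from 260.9 ± 64.4 CPM in VX_Veh to 592.2 ± 43 in VX_SHU (SD, n = 4), by 1.18 ± 0.156 on the log2 scale (SE; edgeR adjusted p = 0.046), and was the 1 gene of 16682 to pass. It lies on chromosome 6 from 135362550 to 135383173 of mm10. The Emp1 level in VX_SHU was near that of both sham groups (531.6 ± 81.4 CPM in Sham_Veh, 618.9 ± 53.5 in Sham_SHU), so that the VX_Veh libraries stood lowest. The genes next in rank did not pass: Trp53inp2, an autophagy protein gene (1.00, adjusted p = 0.17), Tph2, of serotonin synthesis and at low level here (2.46, adjusted p = 0.396), the receptor gene S1pr3 (0.53) and A430033K04Rik (−0.69). Lep was at 395.6 ± 185 CPM in VX_Veh and 705.7 ± 195 in VX_SHU (log2 difference 0.83, edgeR adjusted p = 0.427). Fasn (0.36), Scd1 (0.37), Pparg (0.18) and Adipoq (0.24) did not pass.

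In this comparison 12 of 35 lists were called, all up, and 0 with a correlation estimated per list. Of 27 extracellular matrix genes 13 rose adjusted over the list alone and 0 over all genes, among them Lox, which crosslinks collagen (0.59 ± 0.133), and Col1a1 (0.50 ± 0.113). The list gave 1.09e-16, and adjusted p = 0.162 with an estimated correlation. Macrophage markers had 2 of 20 members up adjusted over the list alone, Ccr2 (0.66 ± 0.157) and Mrc1 (0.45 ± 0.123); the list gave 9.68e-11, and adjusted p = 0.391 with an estimated correlation. Of 14 genes linked to fat mass 4 rose adjusted over the list alone, among them Mest (1.70 ± 0.392) and Npr3 (0.86 ± 0.291). The list gave 6.13e-09, and adjusted p = 0.162 with an estimated correlation. Of 22 cholesterol genes 1 rose adjusted over the list alone, Hmgcs1 (0.74 ± 0.179), with a list median of 0.38 (0.24 without VX_Veh1 and 0.59 without VX_Veh4); the list gave 3.57e-06, and adjusted p = 0.391 with an estimated correlation. Lipolysis had G0s2, an inhibitor of adipose triglyceride lipase (0.79 ± 0.195), and stromal cells Dpt (0.62 ± 0.173) as the 1 member each that rose adjusted over the list alone, and adjusted p = 0.6 and adjusted p = 0.43 with an estimated correlation.

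The other called lists had 0 members past the threshold either way. They were adipocyte identity (median 0.35), endothelial markers (0.28), triglyceride assembly (0.31), insulin signalling (0.20), fatty acid synthesis (0.32) and inflammatory mediators (0.25), and adjusted p = 0.487, 0.6, 0.6, 0.43, 0.774 and 0.57 in that order with an estimated correlation. With epididymis, testis and ciliary marker sums as covariates, an alternative chosen after the data were seen, the median of fatty acid synthesis turned to −0.15 (camera adjusted p = 0.0465), and with an 8-gene ciliary sum to −0.13 (adjusted p = 0.482). That of lipolysis turned to −0.0133 with the former (adjusted p = 0.952 by camera). Without VX_Veh1, the library with the highest ciliary sum, the medians were 0.16 for adipocyte identity, 0.13 for endothelium and 0.145 for triglyceride assembly. Without VX_SHU3 they were 0.22 for adipocyte identity and 0.20 for triglyceride assembly, without VX_SHU1 0.16 for endothelium, and without VX_Veh3 0.505 for fatty acid synthesis and 0.39 for lipolysis. The ciliary gene sum was lower here too, at 71.62 CPM in VX_SHU against 545.8 in VX_Veh. Emp1 passed when Sham_Veh3 or VX_Veh2 was left out (adjusted p = 0.0298 and 0.00231), and with any other library left out its adjusted p was 0.103 to 0.345, with a log2 fold change of 1.09 to 1.225 against 1.18. The call of fatty acid synthesis was lost without VX_Veh1, VX_Veh4 or VX_SHU3 (adjusted p = 0.228, 0.0552 and 0.526; medians 0.11, 0.34 and −0.06, the last of opposite direction), that of lipolysis without VX_Veh1 (0.092), and that of inflammatory mediators without any library other than VX_Veh2, VX_SHU1 and VX_SHU2 (0.0528 to 0.228).

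The third comparison asked what sDVX did under vehicle infusion. With the preset correlation fatty acid synthesis genes were called up as a list and genes linked to fat mass down, while 0 lists were called with an estimated one and 0 genes passed singly. In the first list Scd2 (0.99 ± 0.259 on the log2 scale) was the 1 of 22 members that rose adjusted over the list alone (list median 0.46; 7.04e-08, and adjusted p = 0.632 with an estimated correlation). In the second, 5 of 14 members fell adjusted over the list alone, among them the imprinted gene Mest (−1.06 ± 0.386), Lpgat1 (−0.57 ± 0.190) and the caveolin gene Cav1 (−0.42 ± 0.150), and the list (median −0.39, and −0.20 without VX_Veh1) gave 3.18e-05, and adjusted p = 0.632 with an estimated correlation. By edgeR 0 of 16682 genes passed (smallest adjusted p = 0.209), 1335 had an unadjusted p under 0.05 where chance gives 834, and DESeq2 called 11 and limma-voom with sample weights 7. Emp1 had the smallest p (−1.03, 260.9 ± 64.4 against 531.6 ± 81.4 CPM), followed by the interferon-inducible Ifi204 (−0.58), the integrin gene Itga4 (−0.44), the complement gene C6 (−1.15) and Znrf2 (−0.44). Lep (−0.28), Adipoq (−0.32), Pparg (−0.21), Fasn (1.04) and Scd1 (0.19) did not pass.

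A further 15 lists were called in this comparison with 0 members past the threshold either way and adjusted p from 0.632 to 0.737 with an estimated correlation. Down were macrophage markers (median −0.25), extracellular matrix (−0.16), cell cycle (−0.48), adipocyte identity (−0.27), lipolysis (−0.24), breakdown of branched chain amino acids (−0.10), insulin signalling (−0.11) and testis and sperm markers (−2.94). Up were cholesterol synthesis (0.30), thermogenic genes (0.43), oxidative phosphorylation (0.09), immediate early genes (0.21), circadian clock (0.10), glycolysis (0.13) and mural cells (0.21). The median of the cell cycle list was −0.13 without Sham_Veh4 (adjusted p = 0.0235 by camera), the library with the highest score of this list. The median of the testis markers was 0.20 without Sham_Veh4 (adjusted p = 0.25), the library with 2953 CPM of these markers, and adjusted p = 0.0504 without VX_Veh2. It also turned with 1 surrogate variable (0.59), 2 marker covariates (0.17) or 3 (0.17, and 0.18 with the 8-gene ciliary sum). Without VX_Veh1 the medians were −0.11 for macrophages, −0.10 for matrix, 0.20 for glycolysis and 0.18 for oxidative phosphorylation, and without Sham_Veh3 −0.15 for macrophages, −0.10 for adipocyte identity, 0.22 for glycolysis and 0.18 for oxidative phosphorylation. Without VX_Veh3 they were −0.37 for lipolysis, −0.17 for insulin signalling and −0.25 for branched chain amino acids, and the last gave −0.19 and −0.18 without Sham_Veh1 and VX_Veh2. The clock gave 0.16 to 0.20 without Sham_Veh3, Sham_Veh4, VX_Veh2 or VX_Veh3, and thermogenic genes 0.68 without VX_Veh4. Thermogenic genes gave adjusted p = 0.0633 without VX_Veh3, cholesterol synthesis 0.0515 without VX_Veh4, and adipocyte identity 0.569 without VX_Veh1. Lipolysis gave 0.365 without Sham_Veh3 and 0.541 without VX_Veh1, insulin signalling 0.365 and 0.686, and branched chain amino acids 0.924 and 0.793 without the same libraries, the last with a median of opposite direction (0.03), as without the 6 libraries rich in epididymis or testis markers (0.03). Glycolysis gave 0.102, 0.0681, 0.131 and 0.26 without Sham_Veh1, Sham_Veh2, VX_Veh2 and VX_Veh3, and oxidative phosphorylation 0.0905, 0.0531, 0.0504 and 0.259 without Sham_Veh1, Sham_Veh4, VX_Veh2 and VX_Veh3. Immediate early genes gave 0.102, 0.0594 and 0.145 without Sham_Veh1, Sham_Veh2 and VX_Veh4, and mural cells 0.0536 to 0.432 without Sham_Veh1, Sham_Veh2, Sham_Veh4, VX_Veh2, VX_Veh3 or VX_Veh4. Leaving out VX_Veh2 gave 1 called gene in place of 0.

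The fourth comparison asked what sDVX did under SHU9119. With the preset correlation proliferation genes were called down, and macrophage markers and the joint list of granulocyte and mast cell markers up, and with an estimated one 0 lists were called. All 28 members of the cell cycle list were lower in VX_SHU than in Sham_SHU (median −0.67), and Mki67, a marker of dividing cells, was the 1 that fell adjusted over the list alone, from 22.48 ± 4.67 to 11.44 ± 3.96 CPM (SD, n = 4; −0.97 ± 0.238). The list gave 9.95e-11, and adjusted p = 0.576 with an estimated correlation. Of 20 macrophage markers 4 rose adjusted over the list alone, among them Mpeg1 (0.60 ± 0.141) and Gpnmb (2.05 ± 0.511), and the list gave 7.53e-08, and adjusted p = 0.576 with an estimated correlation. Of 16 granulocyte and mast cell markers 3 rose adjusted over the list alone, the mast cell protease genes Cma1 (1.27 ± 0.333), Mcpt4 (1.18 ± 0.374) and Tpsb2 (1.09 ± 0.352), with 0.0102, and adjusted p = 0.576 with an estimated correlation.

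By edgeR 0 genes passed in this comparison (smallest adjusted p = 0.294), 1778 had an unadjusted p under 0.05, and DESeq2 called 93 and limma-voom 783. The smallest p were those of Numbl (0.50 ± 0.0816), Mc1r, a melanocortin receptor gene, from 1.102 ± 0.186 to 3.286 ± 0.605 CPM (1.57 ± 0.271), Srpx (0.68 ± 0.118), Hexim1 (0.41) and Islr (0.41). Lep (−0.53), Scd1 (−0.79), Fasn (−0.44), Pparg (−0.20) and Adipoq (−0.07) did not pass. Among the lists, genes linked to fat mass had 2 of 14 members down adjusted over the list alone (Fgf13 −1.54 ± 0.418 and Lpgat1 −0.60 ± 0.190), and triglyceride assembly 1 of 19 (Vldlr, −0.46 ± 0.117), and adjusted p = 0.576 and adjusted p = 0.687 with an estimated correlation. Immediate early genes had Jund up (0.39 ± 0.0984), mural cells Tagln up (0.94 ± 0.264), and the extracellular matrix list, called down (median −0.27), Mmp2 up (0.70 ± 0.155), a protease that degrades matrix, each as the 1 member past the threshold over the list alone. Each of these 3 had adjusted p = 0.576 with an estimated correlation. Cholesterol synthesis (−0.33), glycolysis (−0.29), fatty acid oxidation (−0.20) and testis markers (−2.23) were called down, and B cells (0.47), mesothelium (0.38) and endothelium (0.12) up, with 0 members past the threshold and adjusted p from 0.576 to 0.723 with an estimated correlation. Without Sham_SHU3, the SHU9119 library richest in testis markers at 1465 CPM, that list had a median of −0.30 (adjusted p = 0.187). Without Sham_SHU2, matrix (adjusted p = 0.119), glycolysis (0.0622), granulocytes and mast cells (0.0608), B cells (0.067), triglyceride assembly (0.0796), fatty acid oxidation (0.0608), mesothelium (0.0686) and endothelium (0.219) were not called. Without VX_SHU1 the same held for granulocytes and mast cells (0.0652), immediate early genes (0.0652) and endothelium (0.526), and without VX_SHU2 for matrix (0.0588), B cells (0.265) and endothelium (0.113). Without Sham_SHU1 it held for triglyceride assembly (0.117), fatty acid oxidation (0.117) and mesothelium (0.567), without VX_SHU4 for the first pair of these (0.376 and 0.32), and without Sham_SHU4 for immediate early genes (0.0707). Endothelium also gave 0.0547, 0.0683, 0.205 and 0.147 without Sham_Veh2, Sham_Veh4, Sham_SHU3 and Sham_SHU4. Without VX_SHU4 the medians were 0.19 for granulocytes and mast cells in place of 0.41, 0.21 for endothelium and −3.35 for testis markers, and without VX_SHU3 −0.38 for triglyceride assembly in place of −0.19 and −0.32 for fatty acid oxidation. Without Sham_SHU3 they were −0.31 for triglyceride assembly and 0.74 for mesothelium, without Sham_SHU2 −0.20 for cholesterol and 0.36 for immediate early genes in place of 0.23, without VX_SHU2 0.13 for the latter, and without Sham_SHU1 0.23 for endothelium. With 1 surrogate variable the testis median was 0.07. Leaving out Sham_Veh4 gave 3 called genes in place of 0, and leaving out Sham_SHU2 gave 9 called lists in place of 15.

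The interaction asked whether the SHU9119 effect differed between sham and sDVX mice. With the preset correlation, the lists of cholesterol and fatty acid synthesis had the smaller SHU9119 effect after sDVX, and 0 lists were called with an estimated one. Triglyceride assembly was not called, with medians of 0.33 in sham and 0.31 in sDVX mice. Medians with SHU9119 had opposite directions in sham and sDVX mice for macrophage markers (−0.14 and 0.37) and for granulocyte and mast cell markers (−0.52 and 0.23). The macrophage list was not called in sham mice, nor the granulocyte and mast cell list after sDVX. All 22 cholesterol genes had a negative interaction (median −0.57), with 0 past the threshold over the list alone, at 8.55e-11, and adjusted p = 0.16 with an estimated correlation. In fatty acid synthesis the interaction of Scd2 (−1.67 ± 0.365) was the 1 of 22 that passed over the list alone (median −0.82; 1.07e-10, and adjusted p = 0.325 with an estimated correlation). Of 20 macrophage markers 1 passed over the list alone, Mpeg1 (0.77 ± 0.199), with a list median of 0.58 at 4.65e-18, and adjusted p = 0.16 with an estimated correlation. Of 16 granulocyte and mast cell markers 4 passed over the list alone, Cma1 (1.83 ± 0.468), Mcpt4 (1.79 ± 0.526), Cpa3 (1.23 ± 0.391) and Tpsb2 (1.45 ± 0.494), at 0.000118, and adjusted p = 0.325 with an estimated correlation. Cma1 averaged 8.218 CPM in Sham_Veh, 4.175 in Sham_SHU, 5.576 in VX_Veh and 10.08 in VX_SHU. The chymase genes Cma1 and Mcpt4 are related copies whose reads the counting could have split.

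The other called lists had 0 members past the threshold either way. Down were glycolysis (−0.42), thermogenic genes (−0.61), oxidative phosphorylation (−0.19) and cell cycle (−0.11), and adjusted p = 0.363, 0.16, 0.693 and 0.705 in that order with an estimated correlation. Up were T and NK cells (0.40), B cells (0.70), endothelium (0.16), stromal cells (0.12), adipocyte identity (0.20) and mesothelium (0.33), and adjusted p = 0.325, 0.525, 0.75, 0.525, 0.705 and 0.693 in that order with an estimated correlation. The cell cycle median was −0.52 without Sham_Veh4, −0.21 without VX_SHU3, −0.07 without Sham_SHU2 and −0.05 without VX_Veh1, and that of thermogenic genes −0.40 without VX_Veh1. That of oxidative phosphorylation was −0.11, −0.11 and −0.12 without Sham_SHU1, Sham_SHU2 and VX_SHU4, and −0.28 without Sham_Veh3 or VX_SHU3. B cells gave 0.35 without Sham_Veh3, the library richest in these markers in its group, and 0.32 without VX_SHU2, and granulocytes and mast cells 0.33 without Sham_Veh3 in place of 0.68. Endothelium gave 0.25 without Sham_Veh1, Sham_SHU1 or VX_SHU4, and mesothelium 0.73 without Sham_SHU3 and 0.54 without Sham_Veh4. Adipocyte identity gave 0.10 without Sham_SHU4, and its median turned to −0.02 without Sham_Veh3 and −0.09 without the 6 libraries rich in epididymis or testis markers, as did that of endothelium (−0.000492) without VX_Veh1. Adipocyte identity was not called without Sham_Veh3, Sham_SHU3, VX_Veh1, VX_SHU1 or VX_SHU3 (adjusted p = 0.0665 to 0.945), and cell cycle without Sham_Veh1, Sham_Veh2, Sham_Veh3, Sham_SHU1, VX_Veh3, VX_SHU2 or VX_SHU4 (0.0531 to 0.284). Endothelium was not called without Sham_Veh3, Sham_SHU2, Sham_SHU3, Sham_SHU4, VX_Veh1 or VX_SHU1 (0.0586 to 0.945), and stromal cells without Sham_Veh3, Sham_SHU1, Sham_SHU3 or VX_Veh1 (0.0643 to 0.316). Mesothelium was not called without Sham_Veh1, Sham_Veh3, Sham_SHU1, Sham_SHU2, VX_Veh1, VX_SHU1, VX_SHU2 or VX_SHU4 (0.0524 to 0.717).

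By edgeR 0 genes showed an interaction (smallest adjusted p = 0.612), 794 had an unadjusted p under 0.05 where chance gives 834, and DESeq2 called 8 and limma-voom 13. The smallest p were those of Srpx (0.99 ± 0.166), Ifi204 (0.79 ± 0.146), Arhgap15 (1.04 ± 0.202), Numbl (0.55 ± 0.115) and Scd2. Lep (−0.25), Adipoq (0.25), Pparg (0.00), Fasn (−1.48) and Scd1 (−0.98) did not pass. Of the 19 genes called in sham mice, 18 had the same sign after sDVX, all 19 had a smaller effect there, 13 had an unadjusted interaction p under 0.05 and 0 an adjusted one. The slope of the sDVX on the sham effect over them was 0.465. These genes were picked by their sham values, which by itself favours a smaller effect elsewhere. Across all tested genes the 2 SHU9119 effects, which share no library, correlated at 0.729, and genes are not independent replicates. The ciliary gene sum was on average lower with SHU9119 after both surgeries (57.5 against 337.5 CPM after sham surgery, 71.62 against 545.8 after sDVX). The correlation therefore cannot tell an effect on fat cells from a difference in other tissue that both comparisons share. Leaving out Sham_Veh4 gave 1 gene with an interaction in place of 0.

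**Figure D3:**
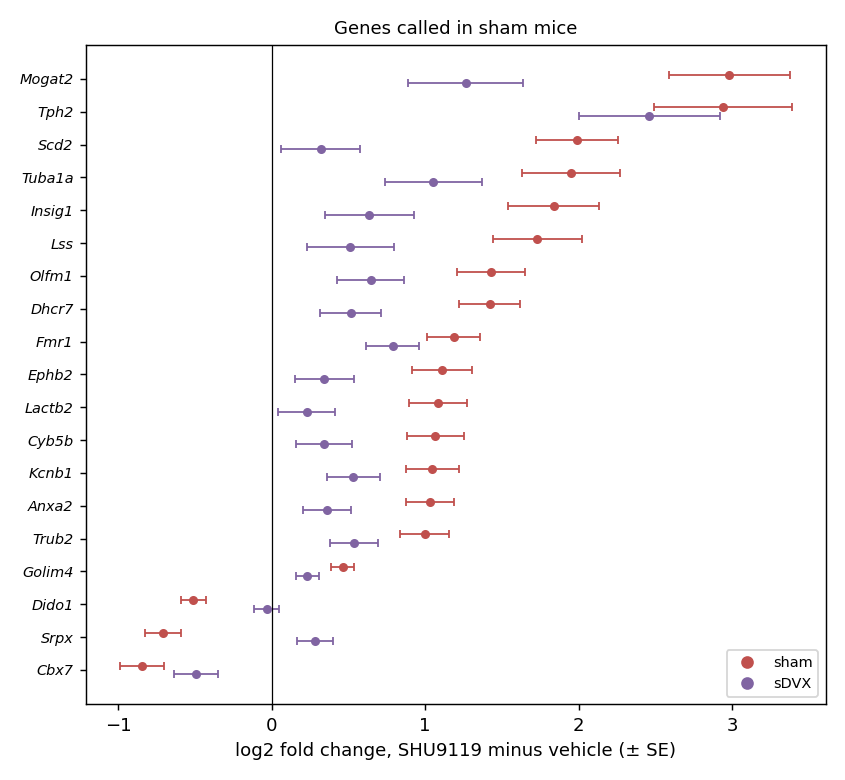
Log2 fold change with SHU9119 after sham surgery and after sDVX of the 19 genes called in sham mice; bars are standard errors from the edgeR fit. All 19 have a smaller effect after sDVX, Insig1 for example 0.64 against 1.84, and 0 of the 19 pass in the interaction.

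Averaged over both surgeries, the SHU9119 effect took in 312 genes, 251 higher and 61 lower (edgeR). Mest, an imprinted gene whose fat level follows depot expansion, rose by 1.54 ± 0.275 on the log2 scale (SE; edgeR adjusted p = 0.0301). Mogat2 (2.12 ± 0.271), the klotho-family gene Lctl (1.58 ± 0.328) and Gys2, a glycogen synthase (1.57 ± 0.337), were the others with the largest increases. The increases of Lctl and Gys2 were mostly those of sham mice. Lctl went from 4.088 to 24.67 CPM there and from 4.748 to 7.039 after sDVX. Gys2 went from 8.821 to 52.75 and from 16.22 to 23.83 CPM, and in VX_SHU only VX_SHU3 was high (52, the others 13.62 to 15.73). Net1, an exchange factor for small GTPases, fell by 1.20 (SE 0.251), Rassf6 fell by 0.85 (SE 0.158) and Echdc2 fell by 0.76 (SE 0.177). Lep (0.96 ± 0.262, adjusted p = 0.0656), Fasn (1.10, adjusted p = 0.0826), Scd1 (0.86, adjusted p = 0.0832), Pparg (0.18) and Adipoq (0.11) did not pass.

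Of 22 cholesterol genes 7 rose over all genes and 15 adjusted over the list alone, such as Dhcr7 (0.97 ± 0.140), Hmgcs1 (0.78 ± 0.127) and Insig1 (1.24 ± 0.206). The list gave 1.97e-15, and adjusted p = 0.121 with an estimated correlation. Of 27 matrix genes 11 rose over all genes and 17 adjusted over the list alone, among them the collagens Col6a1 (0.55 ± 0.0911), Col6a2 (0.74 ± 0.123) and Col1a1 (0.42 ± 0.0796), at 2.58e-15, and adjusted p = 0.121 with an estimated correlation. Genes linked to fat mass had 4 of 14 up over all genes and 10 adjusted over the list alone (Mest, Bmp3 at 1.49 ± 0.301, Npr3 at 0.99 ± 0.206), with 1.17e-08, and adjusted p = 0.136 with an estimated correlation. Fatty acid synthesis had 2 of 22 up over all genes, Scd2 and Pgd, and 13 adjusted over the list alone, and adjusted p = 0.525 with an estimated correlation. Triglyceride assembly had 2 of 19 (Dgat2 0.92 ± 0.185, Agpat2 0.97 ± 0.222) and 7, and glycolysis 1 of 20 (Pfkp, 0.45 ± 0.0804) and 8, by the same counts, and each adjusted p = 0.732 with an estimated correlation. Cell cycle (median 0.14) had Mki67 (0.73 ± 0.168) up either way, lipolysis 3, insulin signalling 2 and adipocyte identity 2 up adjusted over the list alone, and adjusted p = 0.754, 0.754, 0.732 and 0.732 in that order with an estimated correlation. Oxidative phosphorylation (0.15), endothelium (0.17) and fatty acid oxidation (0.14) were called up with 0 members past the threshold, and mesothelium down (−0.34) with 2 of 14 down adjusted over the list alone, and adjusted p = 0.755, 0.754, 0.755 and 0.732 in that order with an estimated correlation. With epididymis, testis and ciliary marker sums as covariates, chosen after the data were seen, oxidative phosphorylation and lipolysis had medians of −0.0184 and −0.0183 (adjusted p = 0.864 each by camera), and fatty acid oxidation of −0.0106 (adjusted p = 0.843). The cell cycle median was 0.43 without Sham_Veh4, 0.08 without Sham_Veh3 and 0.09 without VX_SHU3, that of fatty acid oxidation 0.22 without Sham_Veh3, and that of lipolysis 0.15 without VX_Veh1 in place of 0.23. The mesothelium call was lost without Sham_Veh3, Sham_SHU1 or VX_Veh2 (adjusted p = 0.0551, 0.0669 and 0.0589).

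As 1 mean score per library, an exact permutation test within surgery, chosen after the data were seen, gave higher matrix (0.43 ± 0.0896, p = 0.000408, adjusted p = 0.0143), fat mass (0.65 ± 0.132, adjusted p = 0.0143) and cholesterol scores (0.62 ± 0.115, adjusted p = 0.019) with SHU9119, and fatty acid synthesis did not pass (0.66, adjusted p = 0.111). The p of the matrix score is the smallest that the 4900 assignments can give. In each of the 16 fits without 1 library all 312 genes kept their sign, with a median size of 0.471 to 0.553 against 0.514. These fits too share most libraries with the full fit that picked the genes, which favours the same sign. The 312 calls became 13, 34, 17 and 441 without Sham_Veh1 to Sham_Veh4 in order, 15, 12, 1612 and 3 without Sham_SHU1 to Sham_SHU4, 205, 244, 3 and 859 without VX_Veh1 to VX_Veh4, and 11, 113, 10 and 380 without VX_SHU1 to VX_SHU4. With epididymis, testis and ciliary marker sums as covariates, an alternative chosen after the data were seen, 0 genes were called, and all 312 kept their sign with a median size of 0.397 against 0.514.

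Averaged over both infusions, proliferation genes were called down as a list with the preset correlation, while with an estimated correlation (adjusted p = 0.516) and as a score per library (exact permutation, adjusted p = 0.0714) they were not. Of 28 cell cycle genes 15 fell adjusted over the list alone and 0 over all genes, among them Mki67 (−0.77 ± 0.168) and Top2a (−1.22 ± 0.30), a topoisomerase of dividing cells. The list gave 1.03e-10, and adjusted p = 0.516 with an estimated correlation. As a score per library it gave −0.56 ± 0.164 (exact permutation p = 0.00204, adjusted p = 0.0714). This score was 3.50 in Sham_Veh4, which held 2953 CPM of testis markers, against 2.22 to 2.50 in the other Sham_Veh libraries. In Sham_SHU3, with 1465 CPM, it was 3.05, against 2.96 to 3.05 in the other Sham_SHU libraries. A contribution of testis RNA to the score was not tested. Genes linked to fat mass had 3 of 14 down adjusted over the list alone (Lpgat1 −0.59 ± 0.134, Mest −0.91 ± 0.271) and matrix genes 3 of 27 (Sparc −0.45 ± 0.122), and adjusted p = 0.516 and adjusted p = 0.814 with an estimated correlation. Smooth muscle and mural cells had 6 of 13 up, such as Tagln (0.69 ± 0.186) and Myh11 (0.60 ± 0.192), and immediate early genes 1 of 24, Jund (0.28 ± 0.0696), and adjusted p = 0.659 and adjusted p = 0.922 with an estimated correlation. Testis markers (−2.49), breakdown of branched chain amino acids (−0.12), lipolysis (−0.17), triglyceride assembly (−0.17), fatty acid oxidation (−0.13) and adipocyte identity (−0.21) were called down and circadian clock (0.12) up with 0 members past the threshold, and adjusted p from 0.814 to 0.922 with an estimated correlation. The testis median was −0.985 without Sham_Veh4 and −1.29 without Sham_SHU3, the libraries richest in these markers, and turned with 1 surrogate variable (0.31), 2 marker covariates (0.18) or 3 (0.08, and 0.10 with the 8-gene ciliary sum). Without VX_Veh1 the medians were −0.15 for matrix in place of −0.25 and 0.26 for mural cells in place of 0.16, without Sham_SHU2 0.33 for mural cells and 0.20 for the clock, and without VX_Veh4 0.17 for immediate early genes in place of 0.26. Triglyceride assembly, lipolysis and adipocyte identity were each not called without Sham_Veh3, Sham_SHU2, VX_Veh1 or VX_SHU4 (adjusted p = 0.0502 to 0.229, 0.0515 to 0.178 and 0.0983 to 0.487). Fatty acid oxidation was not called without these or Sham_SHU1 or VX_Veh4 (0.0784 to 0.304), branched chain amino acids without Sham_Veh3, VX_Veh1 or VX_SHU4 (0.0563 to 0.291), and the clock without Sham_Veh1, Sham_SHU3 or VX_SHU3 (0.0533 to 0.167). By edgeR 0 genes passed (smallest adjusted p = 0.224), 2666 had an unadjusted p under 0.05, and DESeq2 called 409 and limma-voom 127. The smallest p were those of Islr (0.34), Rad50 (−0.34), Rarres2, which encodes the adipokine chemerin (−0.41), Emp1 (−0.55) and Sufu (−0.35). Lep (−0.41), Adipoq (−0.19), Pparg (−0.21), Fasn (0.30) and Scd1 (−0.30) did not pass.

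**Figure D4:**
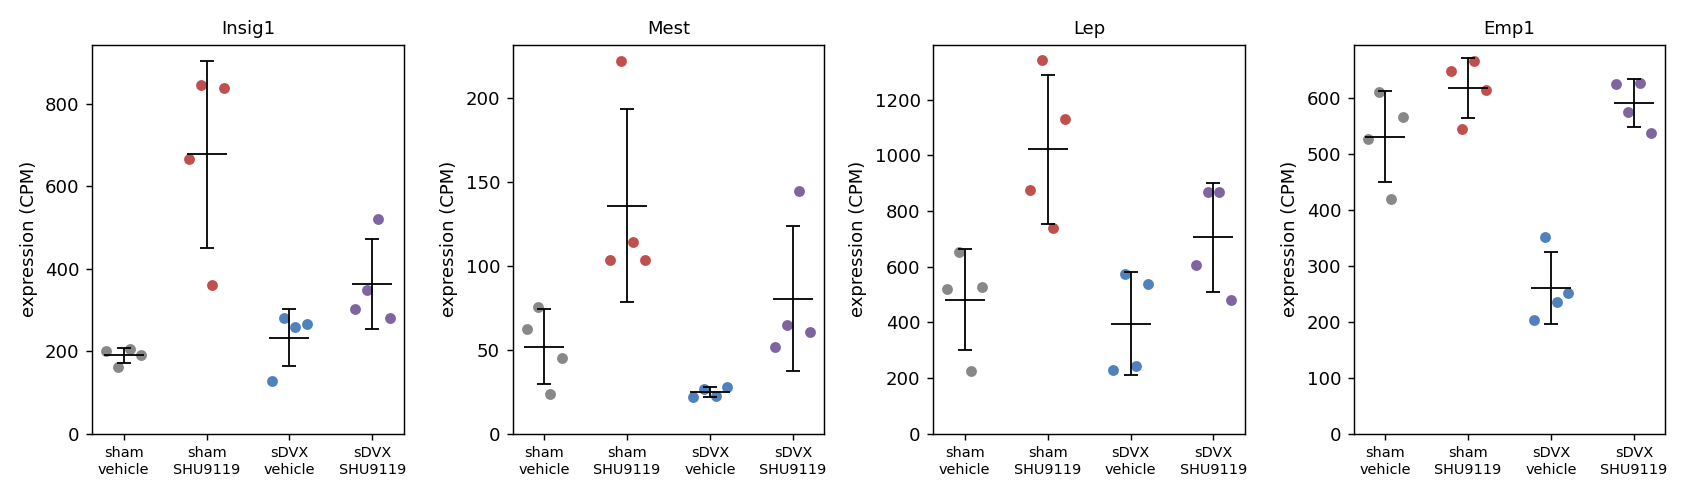
Level of Insig1, Mest, Lep and Emp1 in each library, in CPM; points are libraries, lines are group means and bars are SD (n = 4). Insig1 averages 189.9 CPM in Sham_Veh and 677.7 in Sham_SHU, and Emp1 260.9 in VX_Veh and 592.2 in VX_SHU.

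The sDVX effect under vehicle and the SHU9119 effect in sham mice share the Sham_Veh libraries. Their log2 fold changes correlated at 0.145 across genes (covariance 0.088), while 20 simulations of unchanged groups gave a mean of 0.498, from 0.466 to 0.534 (covariance 0.186), a covariance difference of −0.0982. Over 6 ways of splitting the shared libraries the correlation averaged −0.40, from −0.714 to 0.0131. The sDVX effect under SHU9119 and the SHU9119 effect in sham mice share the Sham_SHU libraries with opposite sign and correlated at −0.128 (covariance −0.0699). The simulations gave −0.508, from −0.535 to −0.467 (covariance −0.191), a covariance difference of 0.122, and the splits 0.164, from −0.323 to 0.641. The simulations drew each gene independently, so their ranges leave out variation that many genes share. They cannot show whether either correlation departs from that of unchanged groups. As sDVX had 0 calls by edgeR under vehicle and under SHU9119, the overlap of its called genes was not tested, and that of DESeq2 or limma-voom calls was not computed.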

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

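The tests of epididymis RNA in 2 vagotomized libraries and of selection by sham values were written before their results were seen. The other tests of this part (interaction without VX_Veh4 and VX_SHU4, random splits, cholesterol score, covariates, raw totals, 10-fold marker counts, Adipoq level) and the ciliated list were chosen after.

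A library far from the other 3 of its group was found 32 times in 228 groups of 4, where chance would give about 11.4 for normal values in independent groups. The values were unlogged CPM and the 228 groups reuse the same 16 libraries, so 11.4 is only a rough guide. For other-tissue markers the value, with the range of the other 3 in parentheses, was, in CPM, for epididymis 11820 in VX_Veh4 (12.47 to 31.64) and 12540 in VX_SHU4 (12.08 to 48.79), and for testis and sperm 2953 in Sham_Veh4 (59.27 to 263) and 1465 in Sham_SHU3 (120.2 to 290.8). The granulocyte and mast cell sum was 1176 in VX_Veh4 (92.11 to 105.4) and 991.9 in VX_SHU4 (82.79 to 129.6), and that of nerve 394.6 in VX_Veh4 (68.93 to 83.2) and 248.9 in VX_SHU4 (65.63 to 71.25). Single genes made up most of both sums: Ltf, a lactoferrin gene of the granulocyte list, stood at 1077 CPM in VX_Veh4 and 876.1 in VX_SHU4, and Npy of the nerve list at 330.8 and 187.7. Ltf had a high loading on the second principal component (−0.0602) with the epididymis gene Crisp1 (−0.0627). In VX_Veh4 and VX_SHU4 the first sum thus mostly followed Ltf and the second Npy, so neither is a measure of granulocytes, mast cells or nerve there. A link of Npy to epididymis was not tested. Ciliated epithelium was at 174.9 in Sham_SHU3 (8.301 to 35.3) and 235.7 in VX_SHU2 (5.337 to 24.86), B cells at 202.5 in Sham_Veh3 (62.8 to 82.88; Jchain alone 158.7), and endothelium at 2585 in Sham_SHU1 (1971 to 2068) and 1359 in VX_Veh1 (2036 to 2125).

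Among named genes the far libraries were, in CPM, Scd2 622.2 in Sham_SHU3 (1172 to 1268), Fmr1 349.4 in Sham_SHU3 (447.4 to 459.2), Dido1 134.9 in Sham_SHU3 (111.6 to 115.1) and 189.1 in Sham_Veh3 (159 to 163.3), Tuba1a 112.5 in Sham_Veh3 (201.5 to 219.7), Scd1 35590 in Sham_Veh3 (18510 to 21340) and Net1 799.3 in Sham_Veh3 (252.4 to 326.8). In VX_Veh1 they were Insig1 129.2 (257.9 to 281.3), A430033K04Rik 11.27 (8.96 to 9.226), Ifi204 20.67 (27.83 to 29.29) and Echdc2 125.2 (62.36 to 69.28). In VX_SHU3 they were Fasn 23850 (7768 to 10450), C6 55.76 (84.99 to 86.42), Gys2 52 (13.62 to 15.73) and Mest 145.1 (51.54 to 64.88). Mest was at 222.1 in Sham_SHU2 (103.7 to 114.2), Rarres2 at 69.28 in VX_Veh2 (57.17 to 59.19), and Ucp1 at 17.81 in VX_Veh3 (0.03474 to 0.174) and 0.04117 in Sham_SHU2 (0 in the other 3). The Ucp1 value in Sham_SHU2 was 1 count.

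By the interaction test, 14 lists had SHU9119 effects that differed between sham and sDVX mice with the preset correlation and 0 with an estimated one. Their median interactions were −0.819 (fatty acid synthesis), −0.422 (glycolysis), 0.199 (adipocyte identity), −0.607 (thermogenic genes), −0.186 (oxidative phosphorylation), −0.57 (cholesterol), −0.113 (cell cycle), 0.577 (macrophages), 0.402 (T and NK cells), 0.702 (B cells), 0.68 (granulocytes and mast cells), 0.161 (endothelium), 0.117 (stromal cells) and 0.333 (mesothelium).

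Other splits of the samples were set beside each count. For the 312 genes of the averaged SHU9119 effect, 4 of 100 splits gave as many, the real one included, which is under 5%. The other 3 of these 4 gave over 3 times as many (highest 3094). Apart from the real one the splits were drawn at random from the possible ones, and this is 1 of 14 such counts without adjustment. Chance is therefore not firmly excluded. For the 19 genes in sham mice, 3 of 35 splits gave as many (highest other 2021), and for Emp1 after sDVX 2 of 35 (highest other 1), so chance cannot be excluded. The splits say nothing about chance for counts of 0, since every split gives as many: sDVX under vehicle (35 of 35; highest other 0), sDVX under SHU9119 (35 of 35; highest other 975), the interaction (100 of 100; highest other 2532) and averaged sDVX (100 of 100; highest other 1194). Splits calling many times the real count point to a structure of the samples other than the groups. For the counts of called lists chance cannot be excluded in any comparison: 20 of 35 splits for the 12 lists in sham mice (highest other 20), 27 of 35 for the 12 after sDVX (20), 10 of 35 for the 17 of sDVX under vehicle (24), 17 of 35 for the 15 under SHU9119 (21), 54 of 100 for the 14 of the interaction (24), 48 of 100 for the 14 of averaged SHU9119 (20) and 55 of 100 for the 12 of averaged sDVX (21).

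Cholesterol synthesis genes were called up as a list with SHU9119 in sham mice (3 of 22 passed over all genes), but adjusted p = 0.0761 with an estimated correlation. A lower share of other tissue would raise all fat cell genes alike, but the cholesterol score less the adipocyte identity score still differed by 0.717 log2 (exact permutation p = 0.0286, the smallest possible). With the 3 marker sums as covariates the list median was 0.797 against 0.868, and with raw library totals 0.706 (exact permutation p of the score = 0.0286). These values argue against each of the 3 as the whole cause. For scaling this covers the TMM factors only, since raw totals change nothing else. The list was taken up after its values in the same libraries were seen, so the exact p-values add no independent support. They are not adjusted over the lists. The cholesterol score itself gave adjusted p = 0.333 by exact permutation in sham mice. An effect of SHU9119 remains as a hypothesis, and body fat, cell sizes and reads shared between gene copies were not tested.

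The 19 genes called in sham mice all had smaller effects after sDVX. For epididymis RNA in VX_Veh4 and VX_SHU4 as the cause the slope was expected above 0.8 without both and was 0.493, but that bound was wrong, since picking genes by their sham values lowers the slope under any cause. Neither epididymis RNA nor selection by sham values can be told apart from a real difference: over the 312 genes of the averaged effect the interaction of the score gave a permutation p of 0.24, and 0.453 without both libraries. Their median effect was 0.592 in sham and 0.409 in sDVX mice, with 262 of 312 smaller after sDVX. A smaller effect after sDVX may exist, but by edgeR 0 genes passed the interaction test, against 8 by DESeq2, 13 by limma-voom and 1 by edgeR without Sham_Veh4.

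Epididymis and testis transcripts stood high in 6 libraries. A wrongly labelled library of another tissue would lack Adipoq, whose lowest level in the 6 was 72.3% of the median of the other libraries of the group. RNA of epididymis in the dissected fat is a candidate source: in each of VX_Veh4 and VX_SHU4, 10 of the 14 tested epididymis genes were at least 10 times the others, short of the 80% set for this test, which keeps it open. Crisp1, the most abundant of them, stood at 7699 and 8231 CPM. No biological explanation was tested, since the design names none for single libraries.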

How the results depend on the processing

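The fits with marker covariates and those without 6 or 2 libraries were chosen after the data were seen, and the other alternatives before. Named genes kept direction and side of the threshold in 5179 values under alternatives other than leaving out a library; 276 came to pass, 172 no longer passed, and 44 that passed in neither fit changed sign. Leaving out single libraries gave 6753, 96, 368 and 15. Most unchanged values of both kinds were of genes that passed in neither fit, such as 6529 of the 6753. Of genes called in the full fit, 224 values stayed called without a single library and 368 did not. For called lists the alternatives other than leaving out a library gave 851 unchanged, 194 no longer called and 11 of opposite direction. Single libraries gave 1396, 137 and 3, with 83 and 78 of the unchanged ones over 1.5 times from the full median.

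By DESeq2 the called genes numbered 1205 (SHU9119 in sham, 19 by edgeR), 54 (SHU9119 after sDVX, 1), 11 and 93 (sDVX under vehicle and SHU9119, 0 each), 8 (interaction, 0), 2792 (averaged SHU9119, 312) and 409 (averaged sDVX, 0). By limma-voom they numbered 3868, 20, 7, 783, 13, 3856 and 127. For SHU9119 in sham mice the count was 0 without the 6 libraries, 101 with 2 covariates, 1 with 3 covariates, 3 without VX_Veh4 and VX_SHU4, and 1 from only the 2 groups compared, which has fewer samples. In these fits all 19 kept their sign, with median sizes of 1.24, 1.14, 1.13, 1.11 and 1.1 against 1.11. The fits without VX_Veh4 and VX_SHU4 and from only the 2 groups keep all sham libraries. Signs and sizes could hardly change there. The ciliated covariate was first taken over 8 genes, which gave 37, so the count depends on which genes make up the covariate. For averaged SHU9119 it was 167 without the filter, 76 with 1 surrogate variable, 4062 without the 6 libraries (293 of the 312 among them), and 0 with 3 covariates of either kind. Emp1 after sDVX was lost (0 calls) with DESeq2 size factors, no filter, 1 surrogate variable, without the 6 or the 2 libraries, with 2 covariates or 3 of either kind, and from only the 2 groups, with a log2 fold change of 1.182 to 1.235 against 1.182. With an estimated correlation 0 lists were called in any comparison. The cause was not tested where none is given.

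With the replicate number as a block, 0 genes were called for SHU9119 in sham mice, after sDVX and averaged, while all 19 and all 312 kept their sign, with median sizes of 1.12 against 1.11 and 0.514 against 0.514, and Emp1 gave 1.199. All groups hold the same replicate numbers, so such a block can hardly move the differences between groups. The kept signs and sizes are therefore no sign of stability. Deviations of same-numbered libraries correlated above 0.1 in 8 of 16 pairs (−0.689 to 0.676), and 5 of 16 libraries correlated best with their own number. The 6 libraries rich in epididymis or testis markers all carry number 3 or 4. Every number 4 library exceeded 500 CPM of epididymis markers (644.7 in Sham_Veh4, 3854 in Sham_SHU4, 11820 in VX_Veh4 and 12540 in VX_SHU4). The correlations therefore cannot decide whether the numbers mark a batch.

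Leaving out 1 library gave 0 to 982 genes for SHU9119 in sham mice, 0 to 1 after sDVX, 0 to 1 for sDVX under vehicle, 0 to 3 under SHU9119, 0 to 1 for the interaction, and 3 to 1612 for averaged SHU9119. Called lists of sDVX under SHU9119 ranged from 9 to 19. The share of sham-called genes with the same sign after sDVX was taken over the genes that each fit itself called, and was 94.7% over 19 in the full fit. It ranged from 50% to 100% over the 8 left-out libraries that left such genes, in fits that called 1 to 982. By limma-voom it was 76.3% over 3868 genes, and without VX_Veh4 and VX_SHU4 it was 66.7% over 3 genes.

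List medians of opposite direction were, for fatty acid synthesis with SHU9119 after sDVX, −0.154 with 3 covariates (adjusted p = 0.0465 by edgeR and camera), −0.128 with the 8-gene kind and −0.0627 without VX_SHU3, and for lipolysis −0.0133 with 3 covariates. For branched chain amino acids in sDVX under vehicle they were 0.0298 without the 6 libraries and 0.0293 without VX_Veh1, and single libraries gave −0.251 to 0.0293. For testis markers in the same comparison they were 0.592 with 1 surrogate variable, 0.171 with 2 covariates, 0.172 and 0.181 with 3 of either kind, and 0.2 without Sham_Veh4, and single libraries gave −3.35 to 0.2. In averaged sDVX the testis list gave 0.309 with 1 surrogate variable, 0.182 with 2 covariates, and 0.0787 and 0.0953 with 3 of either kind, and in sDVX under SHU9119 0.0696 with 1 surrogate variable. In averaged SHU9119, lipolysis gave −0.0183, oxidative phosphorylation −0.0184 and fatty acid oxidation −0.0106 with 3 covariates. In the interaction, adipocyte identity gave −0.02 without Sham_Veh3 and −0.0877 without the 6 libraries, and endothelium −0.000492 without VX_Veh1. Without VX_Veh1 the list test of adipocyte identity turned too while its median kept its direction (0.0069), and single libraries gave −0.02 to 0.275. The cause was not tested.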

Other observations

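The tests of list scores per library and the choice of genes in this part came after the data were seen, and the tests of whole lists were planned.

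Genes of hypoxia and vessel growth split with SHU9119 averaged over surgeries. Of 21 members 1 rose over all genes, Angpt2, a regulator of vessel remodelling (0.46 ± 0.102, edgeR adjusted p = 0.0461), and adjusted over the list alone 6 rose, such as Apln (0.77) and Flt1 (0.30), and 3 fell, the hypoxia-induced Car9 (−0.77), Ankrd37 (−1.47) and Ndrg1 (−0.67). The list was not called (camera adjusted p = 0.281, and adjusted p = 0.778 with an estimated correlation). Of 16 melanocortin and cholinergic genes 4 rose and 2 fell adjusted over the list alone and 0 passed over all genes, among them Mrap, a melanocortin receptor accessory protein (0.74), Mc2r (0.46) and Chrm1 (−1.02). The list was not called (camera adjusted p = 0.233, and adjusted p = 0.732 with an estimated correlation).

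Lists called in no comparison had lowest camera adjusted p of 0.295 (glucocorticoid responsive genes), 0.215 (heat shock and unfolded protein response), 0.21 (hypoxia and angiogenesis), 0.183 (interferon responsive genes), 0.102 (melanocortin and cholinergic components), 0.731 (epididymis), 0.238 (skeletal muscle) and 0.397 (interscapular brown fat). Single members passed adjusted over the list alone: Rnase10 of the epididymis list fell by 3.24 in sDVX under vehicle, Myl1 of the muscle list rose by 0.59 with SHU9119 averaged, and Cdkn1a of the glucocorticoid list rose by 1.19 with SHU9119 in sham mice. Of the hypoxia list 5 rose and 3 fell in that comparison, and Mc1r, a melanocortin receptor gene, rose by 1.18 with SHU9119 after sDVX.

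Ucp1, which uncouples respiration in brown fat, had 505 counts in VX_Veh3 and 0 to 4 in each of the other 15 libraries. Cidea (19.6 CPM) and Cox8b (25.5 CPM) were also highest in VX_Veh3 of the 16 libraries, while Otop1 (1.23 against 2.51 CPM in Sham_SHU1) and Kcnk3 (46.1 against 61.6 CPM in Sham_SHU2) were not.

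As mean scores per library, thermogenic genes gave an interaction of −0.83 ± 0.255 (exact permutation p = 0.00735, adjusted p = 0.257), macrophage markers 0.59 ± 0.221 (adjusted p = 0.321) and cholesterol genes −0.55 ± 0.229 (adjusted p = 0.352), so none passed.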
